A study of Mus musculus with 18 samples.

How the data were processed

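RNA from leukocytes of draining lymph nodes of mice infected with the protozoan parasite Leishmania major was measured on 18 one-colour arrays. Per the labels, the mice were galectin-3 knockout (KO) or C57 wild type (WT), and the titles of the KO arrays name no strain. Nodes were taken 6 hours, 24 hours or 8 days after infection, which gave 6 groups of 3 arrays. No uninfected group was analysed here. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made by the standard Affymetrix procedure. The array design, the genome build and the way animals were pooled, if they were, are not given in the sources used here. Nothing in the labels says which arrays came from separate animals, so the p-values measure the spread between these arrays.

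The deposited values are log2 probe set signals, and the submitters' processing notes name RMA, without a version, as the method that made them. RMA corrects the background, makes the signal distributions of the arrays alike and summarises probes into probe sets, so a change shared by most transcripts on an array would be reduced by it. The log2 scale was taken from the range of the values, 2.16 to 14.42, with no value missing. Which arrays were normalized together is not stated. The table held 1246 probe sets and no Affymetrix control probe sets, so all 1246 were tested. Such a table holds part of the transcriptome only, and a statement about a gene list covers its measured members. Array medians lay between 5.95 and 6.20, and arrays of a group correlated with r of 0.982 or more across probe sets (median 0.991). The smallest root mean square difference between any pair of arrays was 0.207, so no array was a copy of another. For arrays, the number of replicates limits the precision.

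Probe sets carry an accession in their identifier. Genes were named by matching RefSeq accessions, without versions, to a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names and for which genes neighbour each other. The match named 963 probe sets (909 genes, 48 of them with more than 1 probe set) and left 283 unnamed, of which 261 carry a UCSC identifier, 21 a RefSeq and 1 a GenBank accession. Unnamed probe sets entered the tests and are not discussed by gene. The suffix s or x, which marks probe sets that can read several transcripts, was carried by 275 probe sets.

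Differences were computed with limma 3.58.1 in R 4.3.3: lmFit with 6 group means over all 18 arrays, contrasts, eBayes, two-sided moderated tests, and Benjamini-Hochberg adjustment over the 1246 probe sets of a comparison with a threshold of 0.05. The comparisons were KO against WT at each time and averaged over the 3 times, the change of that difference with time (a moderated F test), and 24 hours or 8 days against 6 hours within each genotype. Values are given as the log2 difference ± its standard error (SE), with 3 arrays per group unless stated. Gene lists (cytokine and chemokine groups, markers of cell types, galectins and other lectins, and groups of glycosylation genes) were written down before the data were examined, 33 in all. The 24 lists with at least 5 measured genes were tested with camera (preset correlation 0.01, the brightest probe set per gene, 909 genes as the universe, Benjamini-Hochberg over the lists). The same lists were run with the correlation estimated from the data and with fry. List tests of 24 hours against 6 hours and of the change of the genotype difference with time were added after the data were examined.

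Genes were named in the text by a rule written before the data were examined. Lgals3 comes first. For each comparison the rule takes up to 12 genes higher and 12 lower with the largest log2 difference among those past the threshold, and the 5 named genes with the smallest p where fewer than 5 pass. It adds up to 4 genes per list with the smallest p, and a fixed set for the genotype comparisons (Foxp3, Il10, Il2ra, Tgfb1, Ifng, Il4, Il12b, Notch1, Notch3, Jag1, Dll1, Dll4 and Hes1). No named probe set carried Foxp3 or Il12b, so these were not analysed here.

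The limma step was tested on 20 simulated data sets with the observed means and spreads and 200 of the 1246 probe sets changed. For KO against WT at 1 time it recovered 67.9% of changes of 0.5 on the log2 scale, 93.7% of changes of 1, 98.4% of changes of 1.5 and 99.2% of changes of 2, and 4.01% of its calls were false. For 8 days against 6 hours the shares were 66.1%, 92.3%, 98.3% and 99.3%. Those simulations draw each probe set independently, which real arrays do not do. They also give each probe set 1 spread in all groups. With 200 probe sets changed at once the adjustment is milder than with few changes. The recovered shares therefore do not carry over to a comparison with few calls or none. The alternatives were median centring of each array, a second quantile normalization, leaving out the lowest 30% of probe sets, a trended and robust variance, array weights, the replicate number as a block, only the arrays of the groups compared, the mean of a gene's probe sets in the list tests, and leaving out each array in turn. Array weights were estimated gene by gene, because the default estimate did not converge, a choice made after the data were examined. Leaving out the 2 arrays farthest from their groups (WT at 6 hours replicate 1 and WT at 8 days replicate 3), and a random block for the animal-like code in the titles with statmod 1.5.0, were also added after the data were examined.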

Results

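The data comprised log2 signals of probe sets in lymph node leukocytes of KO and WT mice at 6 hours, 24 hours and 8 days after infection, with 3 arrays in each of the 6 groups. The first principal component held 36.7% of the variance. The design asked how the draining node of mice that lack galectin-3, a beta-galactoside-binding lectin encoded by Lgals3, differed from the WT node over the course of infection.

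The transcript of the targeted gene was examined first. Lgals3, read by the probe set NM_010705.2_psr1_s_at, was detected on the arrays labelled KO at levels close to those of the WT arrays. Its log2 signal was 10.62 ± 0.03 (SD, n = 3) in KO and 11.01 ± 0.53 in WT at 6 hours, 9.89 ± 0.32 and 10.41 ± 0.22 at 24 hours, and 9.89 ± 0.20 and 10.10 ± 0.19 at 8 days. The KO arrays gave 10.61, 10.59 and 10.66 at 6 hours, 9.94, 9.55 and 10.19 at 24 hours, and 9.67, 9.93 and 10.06 at 8 days. The WT arrays gave 10.44, 11.49 and 11.08, then 10.62, 10.42 and 10.18, then 10.20, 9.88 and 10.22. On every one of the 18 arrays it ranked at or above the 90.0th percentile of the probe sets. The KO minus WT difference was -0.39 ± 0.22 (SE) at 6 hours, -0.51 ± 0.22 at 24 hours and -0.21 ± 0.22 at 8 days, and none passed the threshold (adjusted p = 0.670, 0.402 and 0.824). Averaged over the times it was -0.37 ± 0.13, with an unadjusted p of 0.0101 and an adjusted p of 0.589 (limma). The probe positions and the allele are not given in the sources used here, and a probe set outside the deleted part of the gene checks nothing. KO is therefore used below for arrays labelled knockout, and each direction between genotypes rests on those labels.

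**Figure D1:**
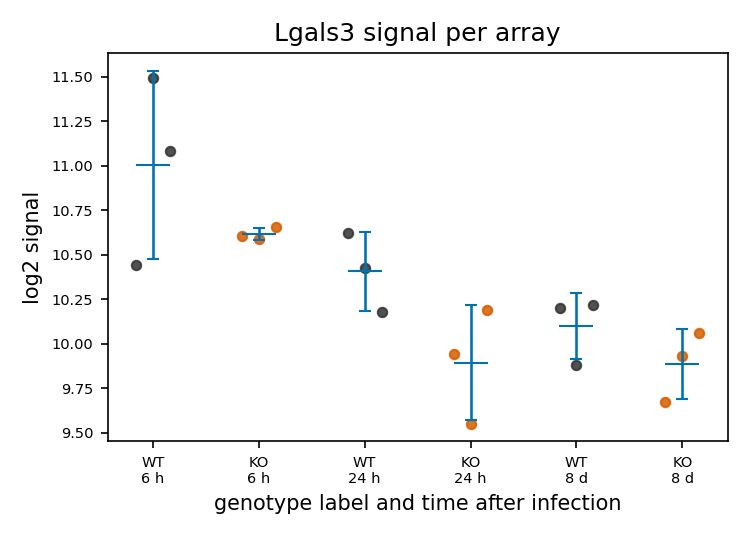
Log2 signal of Lgals3 on each array (vertical axis) by genotype label and time after infection (horizontal axis). Points are arrays, and blue bars give the group mean with its SD (n = 3). The lowest array, a KO array at 24 hours, lay at 9.55 and the highest, a WT array at 6 hours, at 11.49.

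From 6 hours to 8 days in WT, genes of inflammatory cytokines and chemokines were among those with the largest falls, and the cytokine genes Il21 and Il4 and the cell cycle gene Cks2 had the largest rises. Il1b, an inflammatory cytokine, fell by 2.89 ± 0.47 on the log2 scale (adjusted p = 8.3e-04) and Il1a fell by 2.54 ± 0.43 (adjusted p = 0.00119). Of the monocyte-attracting chemokines, Ccl7 fell by 2.78 ± 0.51 (adjusted p = 0.00203) and Ccl3 fell by 2.60 ± 0.41 (adjusted p = 7.4e-04). Areg, which encodes the growth factor amphiregulin, had the largest change, -4.19 ± 1.13 (adjusted p = 0.0180). Il21 and Il4, cytokines made by helper T cells, rose by 1.89 ± 0.18 (adjusted p = 1.9e-05) and 1.76 ± 0.23 (adjusted p = 2.3e-04). Il21 started from a log2 signal of 2.70, near the lowest values of the table. Cks2 and Cks1b, subunits of the kinases that drive the cell cycle, rose by 1.93 ± 0.24 and 1.21 ± 0.17 (adjusted p = 1.9e-04 and 2.8e-04). Other genes with large increases were Hpse (1.30), which encodes heparanase, the sulfotransferase gene Chst3 (1.29), Igf2bp3 (1.29), Havcr1 (1.20), Cd83 (1.17), Ackr4 (1.16) and Fcrla (0.96). Large decreases were also measured for Ccl24 (-2.59), Ccl9 (-2.53), Cxcl10 (-2.39), Ccl4 (-2.27), Igfbp2 (-2.14), the lectin gene Cd209e (-2.06) and the proteoglycan gene Vcan (-2.04).

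In all, 274 probe sets passed, 113 higher and 161 lower at 8 days in WT, with 77 named genes higher and 151 lower. The balance of higher and lower calls moved with the scaling: after median centring of the arrays 289 were higher and 132 lower, and after a second quantile normalization 145 of 246 were higher. The count was 89 when only the arrays of the groups compared were fitted, 177 without the 2 farthest arrays, 143 without WT at 6 hours replicate 1 and 168 without WT at 8 days replicate 1.

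Among the lists, 9 of 25 measured inflammatory chemokine and receptor genes fell and 1 rose in WT at 8 days (10 and 1 adjusted over the list alone). Ccl9, Ccl3, Ccl7 and Cx3cl1 (-0.85) had the smallest p. Of 12 monocyte and macrophage markers 5 fell (6, with 1 higher, adjusted over the list alone), among them the mannose receptor gene Mrc1 (-1.28), Clec4d (-1.63), Mgl2 (-0.80) and Ccr2 (-0.87). All 4 measured B cell markers rose, namely Siglecg (1.11), Fcer2a (0.89), Cd22 (0.80) and Cd72 (0.78). Of 10 dendritic cell markers, Cd83 and Flt3 (0.96) rose and Cd209a (-0.72) fell. No NK cell marker of 10 passed. Of 13 stromal and endothelial markers 5 fell, such as Cd34 (-0.66) and Pdgfra (-0.72), and Madcam1 (0.71) and Icam2 (0.42) rose, but 2 were higher and 2 lower after quantile normalization. Of 13 homeostatic chemokine and receptor genes Cxcr5 (0.78), a receptor that guides cells into B cell follicles, and Cxcr4 (0.84) rose and Cxcl14 (-1.08) fell, with 5 higher and 1 lower after median centring and 3 and 1 after quantile normalization. The Th2 list had 3 higher and 5 lower of 17, the Th1 list 2 and 1 of 17, the Th17 list 1 and 2 of 16, and the regulatory T cell list 0 and 1 of 13. After median centring the Th2, Th1 and Th17 lists had 4 and 5, 4 and 1, and 2 and 2. In the Notch list 2 of 20 rose, Hes5 (0.75) and Hes6 (0.57), and 7 fell, including Notch1 (-0.80) and Dll1 (-0.62), with 2 higher and 4 lower after quantile normalization. No list passed camera in this comparison (smallest adjusted p = 0.202, and 0.952 with an estimated correlation), although 1 list, inflammatory chemokines, passed as lower after median centring and 1 without WT at 6 hours replicate 1.

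Genes of lectins and glycan synthesis changed in both directions in WT. Lgals3 itself fell by 0.91 on the log2 scale and Grifin and Lgals2 rose among the 10 galectin genes (1 higher and 1 lower after quantile normalization). The mean of the same Lgals3 probe set also went from 10.62 at 6 hours to 9.89 at 8 days on the KO arrays. Its fall was thus not particular to WT. Of 9 Siglec genes Siglecg, Cd22 and Siglec15 rose and Siglecf (-0.89) fell (5 higher and 1 lower after median centring), and of 35 C-type lectin receptor genes 3 rose and 10 fell. Counts of higher and lower genes were 2 and 2 of 19 sialyltransferases, 0 and 2 of 10 fucosyltransferases, 1 and 4 of 23 N-glycan branching genes, 2 and 3 of 24 mucin-type O-glycan genes, 5 and 10 of 43 glycosaminoglycan genes, 1 and 8 of 24 proteoglycan core genes, 2 and 3 of 18 selectin and selectin ligand genes, 2 and 4 of 26 lysosomal glycan degradation genes, 1 and 5 of 39 sugar nucleotide genes and 1 and 2 of 18 glycosphingolipid genes. After median centring the lower side no longer led for fucosyltransferases (2 and 0), N-glycan branching (7 and 3), mucin-type O-glycans (4 and 1), glycosaminoglycans (7 and 6), selectin ligands (4 and 3), lysosomal degradation (4 and 3), sugar nucleotides (4 and 4) and glycosphingolipids (3 and 2), so no direction is given for these lists. Of these lists, the lower side still led after quantile normalization for N-glycan branching (3 and 4) and glycosphingolipids (1 and 3). It also led for selectin ligands (3 and 5), and it did not for the others. No direction is given for proteoglycan core genes either, with 4 higher and 7 lower after centring and 1 and 2 after quantile normalization. Single genes with small p were the sialyltransferase gene St6gal1, higher by 0.90, St3gal4 (-0.82), Gcnt2 (-1.35) and Galnt18 (-1.30). Lists with fewer than 5 measured genes were not tested: 1 of 2 plasma cell and 1 of 2 T cell markers fell (none after quantile normalization), none of 3 type I interferon genes, 2 neutrophil markers, 1 integrin and 1 reference gene passed, and no gene of the Toll-like receptor and cell cycle lists was measured.

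Several of the largest falls and rises of WT from 6 hours to 8 days were also called in the KO arrays. Areg, Ccl24, Igfbp2, Cd209e and Vcan, with large falls in WT, were not among the largest falls called in KO. Their falls in KO, if any, were smaller than that of Clec4n (-1.32) or did not pass the threshold. This does not show a difference between the genotypes, since no probe set passed the test of a different time course. The WT arrays at 6 hours also varied widely for Ccl24, Cd209e and Areg, with SDs of 1.35, 1.12 and 1.00, and less for Igfbp2 and Vcan (0.45 and 0.31). Ccl7 fell by 2.91 ± 0.51 (adjusted p = 0.00266), Ccl3 fell by 2.70 ± 0.41 (adjusted p = 0.00103) and Il1b fell by 2.61 ± 0.47 (adjusted p = 0.00311). Falls were also measured for Ccl4 (-2.69), Ccl9 (-2.68), Il1a (-2.45), Cxcl10 (-2.17), Ccl12 (-2.13) and Cxcl2 (-2.02). Clec4d (-2.19), Il1rn (-1.39) and Clec4n (-1.32) fell as well. Cks2 rose by 1.84 ± 0.24 (adjusted p = 2.9e-04), Il21 by 1.81 ± 0.18 (adjusted p = 3.4e-05) and Il4 by 1.49 ± 0.23 (adjusted p = 0.00119). Cd83 (1.59), Hpse (1.56), Chst3 (1.37), Igf2bp3 (1.33), St6gal1 (1.24), Cxcr5 (1.07), Timd2 (1.06), Siglecg (1.06) and Ackr4 (1.06) rose as well. In all, 141 probe sets passed, 77 higher and 64 lower (112 and 54 after median centring). Without 1 array the count was 47 (KO at 8 days replicate 2), 50, 63 and 86 (KO at 6 hours replicates 1, 2 and 3) and 66 (KO at 8 days replicate 3), and array weights gave 443.

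In the KO arrays 9 of 25 inflammatory chemokine and receptor genes fell and 1, Cxcr3 (1.02), rose (10 and 2 adjusted over the list alone). Of 12 monocyte and macrophage markers 4 fell (6 adjusted over the list alone), and 3 of 4 B cell markers rose, with Cd72 at 0.53 (adjusted p = 0.0655). Both falling lists passed camera (adjusted p = 0.00310 and 0.0116), but neither did with an estimated correlation (adjusted p = 0.773 for each) or when the lowest 30% of probe sets were left out. The 8-day changes of WT and KO correlated across probe sets (r = 0.811, rho = 0.618; probe sets are not independent replicates). Of the calls, 44 were shared as higher, where 6.98 would be shared by independent lists, and 52 as lower, where 8.27 would be, and none were opposite. Both comparisons use the same estimate of the spread of each probe set. Their calls are therefore not independent, and the expected counts are likely too low. No probe set passed the test of a different time course between the genotypes (139 with an unadjusted p under 0.05, limma).

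**Figure D2:**
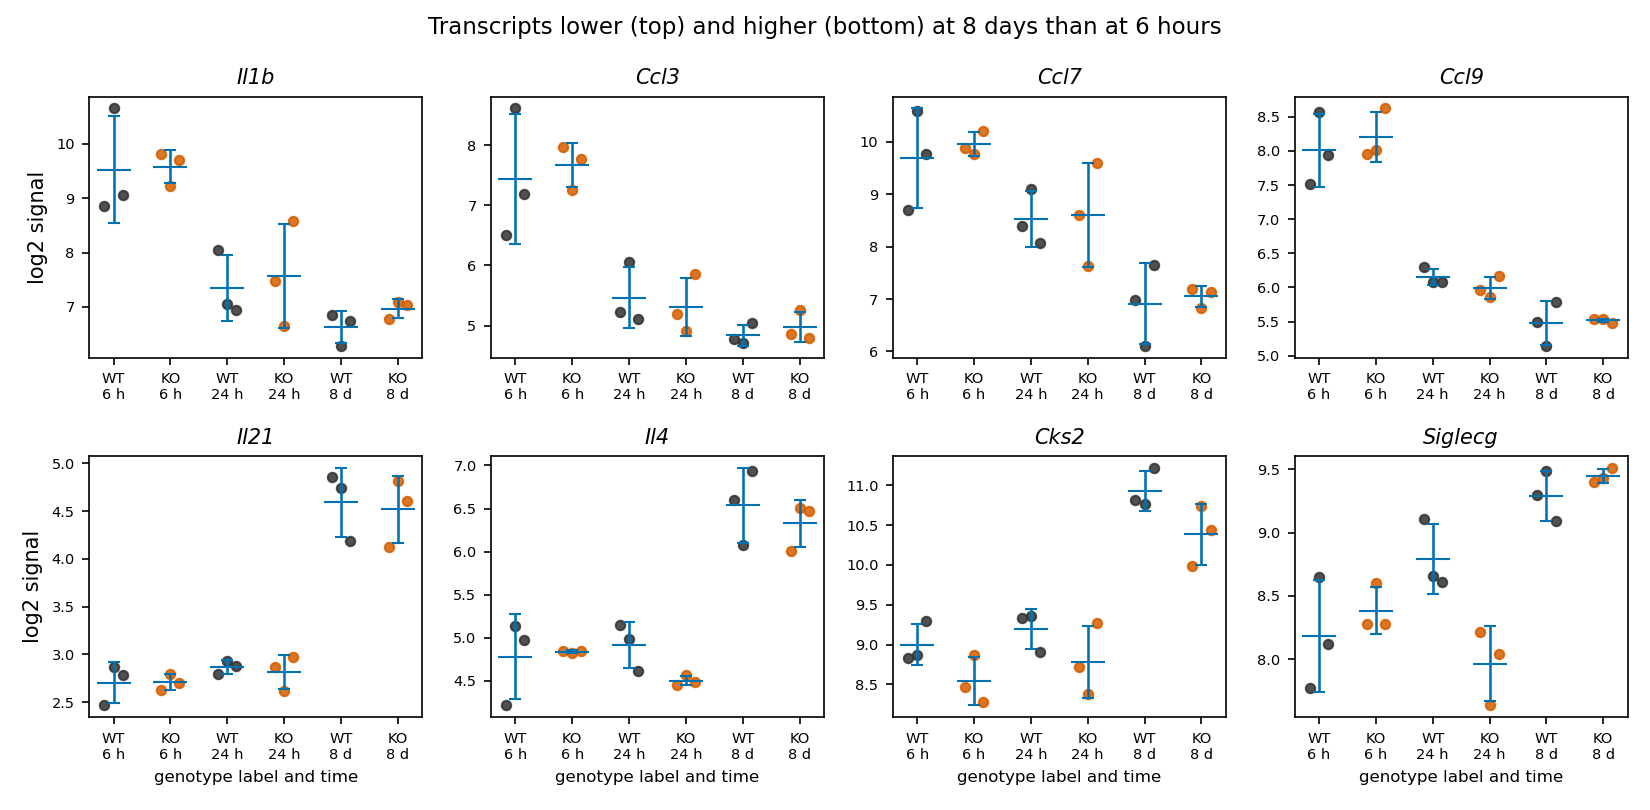
Log2 signal per array (vertical axes) of 8 genes by genotype label and time after infection (horizontal axes). Black points are WT arrays, orange points KO arrays, and blue bars give the group mean with its SD (n = 3). Il1b, Ccl3, Ccl7 and Ccl9 were lower at 8 days than at 6 hours in both genotypes, and Il21, Il4, Cks2 and Siglecg were higher.

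By 24 hours, Il2, the T cell growth factor, and Il3 had risen in both genotypes, and Il1a, Ccl3, Ccl9 and Clec4d had fallen in both. In WT, Il2 rose by 1.54 ± 0.28 (adjusted p = 0.0124), its receptor gene Il2ra by 0.92 ± 0.24 (adjusted p = 0.0488), and the NK receptor gene Klra7 by 1.17 ± 0.28 (adjusted p = 0.0397). Clec2d (0.94), Klra4 (0.89), Gal3st2 (0.66), Angptl7 (0.45) and Il3 (0.44) rose too. Klra4 started from a log2 signal of 2.72 in WT, and Il3 from 3.13 in each genotype, near the lowest values of the table. Il1a fell by 2.50 ± 0.43 (adjusted p = 0.0102), Ccl9 fell by 1.85 ± 0.23 (adjusted p = 9.9e-04) and Vcan fell by 1.69 ± 0.28 (adjusted p = 0.00888). Other falls were those of Ccl24 (-2.18), Il1b (-2.17), Slc35f3 (-2.04), Fgfr2 (-2.02), Ccl3 (-1.97), Cd209e (-1.86), Muc15 (-1.82), Clec4d (-1.63) and Frem1 (-1.43). The starting values of some varied widely between WT arrays at 6 hours, with SDs of 1.35 for Ccl24, 1.32 for Muc15 and 0.86 for Frem1. In KO, Il2 rose by 1.27 ± 0.28 (adjusted p = 0.0450) and Il3 by 0.59 ± 0.12 (adjusted p = 0.0217), and Il1a (-2.52), Ccl3 (-2.36), Ccl9 (-2.21), Clec4d (-1.96), Cxcl2 (-1.92), Cspg4 (-1.10), Papss2 (-0.77), Notch4 (-0.65) and Msmo1 (-0.44) fell. No probe set was called higher in KO with only the 2 groups, without any 1 KO array at 6 hours, or without KO at 24 hours replicate 3. The calls of Il2 and Il3 in KO thus depended on single arrays. In WT the count of higher calls went from 14 to 1 without WT at 6 hours replicate 1 or WT at 24 hours replicate 2. It was 2 without WT at 6 hours replicate 3, and at most 22 without any other array. With the replicate block it was 1 and with only the 2 groups 0, so most calls of rises in WT depended on single arrays as well.

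The WT comparison called 49 probe sets, 14 higher and 35 lower (31 and 43 after median centring, 26 and 33 after quantile normalization). The KO comparison called 11, 2 higher and 9 lower (8 and 10 after median centring). Of these calls 2 were shared as higher and 4 as lower. Of 25 inflammatory chemokine and receptor genes 3 fell in WT (6 lower and 3 higher adjusted over the list alone, and 5 lower and 1 higher after median centring), but 16 of 25 had positive values, with a median of 0.12 and a mean of -0.07, and the list did not pass camera (adjusted p = 0.970). In KO 3 of 25 fell (7 lower and 2 higher adjusted over the list alone), with a median of -0.25 (-0.15 without KO at 6 hours replicate 3 and -0.022 without KO at 24 hours replicate 2). The 10 NK and cytotoxic cell markers all had positive values at 24 hours in both genotypes, with medians of 0.75 in WT and 0.41 in KO. The WT median fell to 0.38 without WT at 24 hours replicate 2, and the KO median to 0.25, with 7 of 10 positive, without KO at 24 hours replicate 3. Of these 1 passed in WT (8 adjusted over the list alone, and 4 after median centring) and none in KO. Other lymphocyte markers moved as well: the 4 B cell markers were all positive in WT (median 0.40) and all negative in KO (median -0.35), and both T cell markers were positive in WT (median 0.35) and in KO (median 0.22). None of these passed, and adjusted over the list alone Siglecg and Cd2 did in WT. Per array, the B and T cell list means overlapped between 6 and 24 hours, except for T cell markers in WT. The T cell mean in KO was 9.55, 9.84 and 9.63 at 6 hours and 10.01, 9.47 and 10.20 at 24 hours. The NK and Th1 lists passed camera as higher in WT (adjusted p = 5.1e-05 and 8.5e-04) and in KO (adjusted p = 0.0202 and 0.0355), but not with an estimated correlation (adjusted p = 0.986 in WT and 0.906 in KO). In KO both calls were also lost without KO at 24 hours replicate 3 (adjusted p = 0.454 and 0.556) or KO at 6 hours replicate 2 (0.0655 and 0.0946), and in WT both were kept without any 1 array. The mean of the Th1 list went from 0.53 to 0.29 in WT without WT at 24 hours replicate 2 and in KO from 0.33 to 0.10 without KO at 24 hours replicate 3 and to 0.53 without KO at 24 hours replicate 2. In KO inflammatory chemokines and C-type lectin receptors also passed as lower (adjusted p = 0.00248 for each, and 0.906 for each with an estimated correlation). The former call was lost without KO at 24 hours replicate 2 (adjusted p = 0.209). The WT count fell to 12 with a replicate block and to 0 when only the 2 groups were fitted, and it was 7 and 13 without WT at 24 hours replicates 2 and 3, and 22, 78 and 12 without WT at 6 hours replicates 1, 2 and 3. The KO count was 4 and 7 without KO at 6 hours replicates 1 and 2, 17 and 7 without KO at 24 hours replicates 2 and 3, 5 with only the 2 groups and 137 with array weights.

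**Figure D3:**
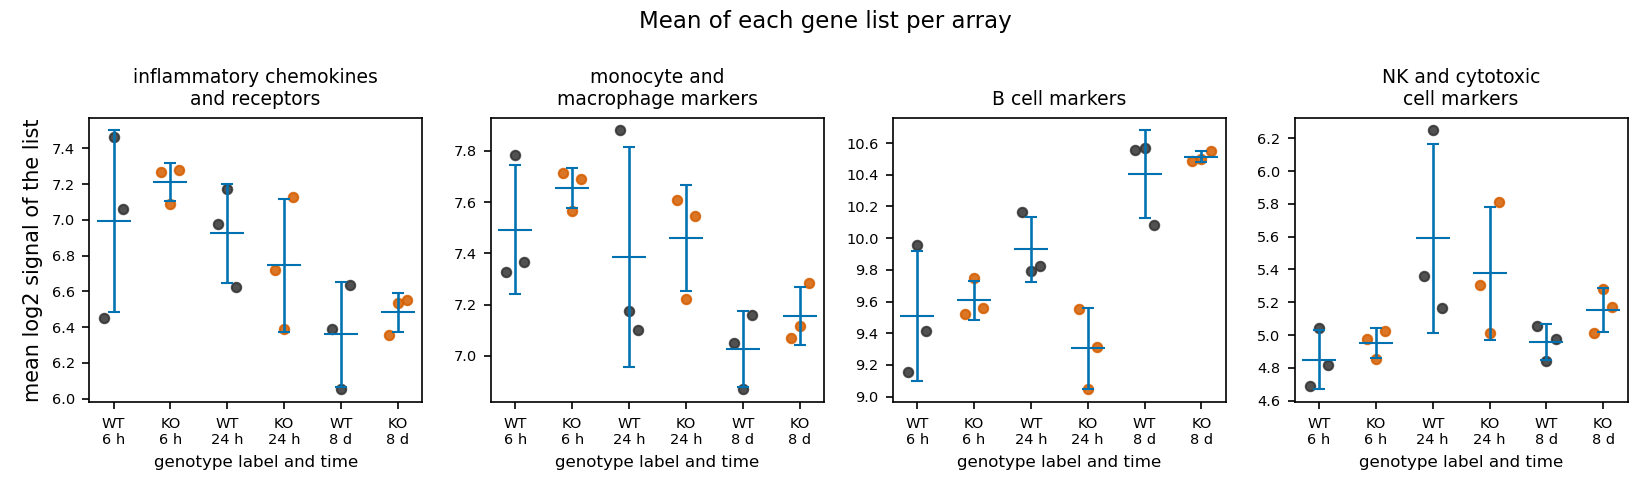
Mean log2 signal of the measured genes of 4 lists on each array (vertical axes) by genotype label and time after infection (horizontal axes). Black points are WT arrays, orange points KO arrays, and blue bars give the group mean with its SD (n = 3). The 2 highest means of NK and cytotoxic cell markers were those of 1 WT array (6.25) and 1 KO array (5.81) at 24 hours.

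Between the genotypes, no probe set passed at any time. At 6 hours the smallest p belonged to genes that were lower in KO: Bdnf, which encodes a neurotrophin (-0.47 ± 0.09, adjusted p = 0.201), Muc15, a membrane mucin gene (-1.76 ± 0.42, adjusted p = 0.344), Cx3cl1, which encodes the chemokine fractalkine (-0.64 ± 0.16), Frem1, an extracellular matrix gene (-1.25 ± 0.32), and Fzd6, a Wnt receptor gene (-0.75 ± 0.19). Muc15 and Frem1 varied widely in WT, with SDs of 1.32 and 0.86. Of the fixed set, Hes1 (-0.47 ± 0.18, adjusted p = 0.497) and Dll1 (-0.41 ± 0.14, adjusted p = 0.491) had the smallest p, and Il10 (0.14), Il2ra (-0.04), Tgfb1 (-0.06), Ifng (0.02), Il4 (0.06), Notch1 (0.09), Notch3 (0.19), Jag1 (-0.06) and Dll4 (0.08) did not pass either. With limma, 109 probe sets had an unadjusted p under 0.05, where 62.3 would by chance, and array weights called 8 and the fit without the 2 farthest arrays 3. Without WT at 6 hours replicate 1 or replicate 2 the count was 2. No list passed camera, and 1 did without WT at 6 hours replicate 1 or 2 or KO at 6 hours replicate 2.

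At 24 hours the smallest p belonged to an unnamed probe set (adjusted p = 0.140). Among named genes the smallest were those of Ogt, which encodes the O-GlcNAc transferase (-0.58 ± 0.13), the cytokine gene Il17a (0.39 ± 0.09), the B cell gene Siglecg (-0.83 ± 0.20), Clec2d (-1.02 ± 0.25) and the glypican gene Gpc1 (1.33 ± 0.33), each with an adjusted p of 0.194. The Il17a signals were near the lowest of the table, 2.88 in KO and 2.49 in WT. All 4 B cell markers were lower in KO, with Cd72 at -0.62, Fcer2a at -0.60 and Cd22 at -0.45 beside Siglecg, and all 4 passed when adjusted over the list alone. Other markers were lower too: 9 of 10 NK and cytotoxic cell markers (median -0.20, camera adjusted p = 0.291), both T cell markers (median -0.15) and 7 of 10 dendritic cell markers (median -0.11). Of 12 monocyte and macrophage markers 7 were higher (median 0.09). Of the fixed set, Il4 (-0.41), Il10 (0.24), Dll1 (-0.15), Dll4 (0.12), Hes1 (-0.09), Ifng (-0.09), Notch3 (0.09), Jag1 (-0.06), Notch1 (-0.05), Il2ra (-0.04) and Tgfb1 (-0.02) did not pass. An unadjusted p under 0.05 was reached by 122 probe sets with limma. The count of calls was 3 without WT at 24 hours replicate 1 and 1 without WT at 24 hours replicate 3 or KO at 24 hours replicate 1. No list passed camera, and 1 did without WT at 24 hours replicate 1 or KO at 24 hours replicate 2, 2 without WT at 24 hours replicate 3 and 3 without KO at 24 hours replicate 3.

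At 8 days the genes with the smallest p were Galnt2, which starts mucin-type O-glycans (0.38 ± 0.10), the proteasome gene Psmb5 (-0.31 ± 0.08), the sialyltransferase gene St3gal1 (0.35 ± 0.09), Siglech, a marker of plasmacytoid dendritic cells (0.90 ± 0.26), and Papss2 (0.48 ± 0.14), each with an adjusted p of 0.720. Of the fixed set, Notch1 (0.51 ± 0.16, adjusted p = 0.720) and Tgfb1 (0.48 ± 0.20, adjusted p = 0.725) had the smallest p, followed by Il2ra (0.43) and Hes1 (-0.24), with Ifng at 0.46, Il4 at -0.21, Jag1 at -0.20, Dll4 at 0.10, Notch3 at 0.06, Dll1 at 0.03 and Il10 at -0.03. The list of regulatory T cell and immune regulation genes, with 9 of 13 positive and a median of 0.37, and that of lysosomal glycan degradation, with 20 of 26 positive and a median of 0.19, passed camera as higher in KO (adjusted p = 0.0158 for each). Both list calls were lost with an estimated correlation (adjusted p = 0.759 and 0.967) and with fry, and also without WT at 8 days replicate 3 or KO at 8 days replicate 3. Neither had a single gene past the threshold, over all probe sets or adjusted over the list alone. The members with the smallest p were Itgae (0.68), Tgfbr2 (0.24), Tgfbr3 (0.37) and Tgfb1 in the former and Gm2a (0.27), Arsa (0.27), Psap (0.23) and Galc (0.24) in the latter. Markers of other cells were higher beside them: both T cell markers (median 0.39, with Il7r at 0.67 past the threshold over the list alone), 8 of 10 dendritic cell markers (median 0.22, camera adjusted p = 0.0540, with 0.0323 after median centring and 0.967 with an estimated correlation), 9 of 10 NK and cytotoxic cell markers (median 0.21) and 9 of 12 monocyte and macrophage markers (median 0.22) had positive values. With limma 82 probe sets had an unadjusted p under 0.05.

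Averaged over the 3 times, no probe set passed either (72 with an unadjusted p under 0.05, limma), and 5 did without WT at 24 hours replicate 1. Galnt2 was higher in KO by 0.28 ± 0.06 (adjusted p = 0.178), and Cd209b, a lectin gene of macrophages, by 0.99 ± 0.22 (adjusted p = 0.204). Hs3st1 (-0.27 ± 0.06), the eosinophil chemokine receptor gene Ccr3 (-0.66 ± 0.17) and Ogt (-0.28 ± 0.07) were lower. Both probe sets of Cd209b were higher in KO at each time, and the other one gave 0.99 ± 0.26. The averaged values of the fixed set were Hes1 -0.27, Il4 -0.19, Notch1 0.18, Dll1 -0.17, Tgfb1 0.13, Ifng 0.13, Il10 0.12, Il2ra 0.11, Notch3 0.11, Jag1 -0.11 and Dll4 0.10. No list passed camera, and 1 did without WT at 6 hours replicate 1 or 3, 3 without WT at 24 hours replicate 1 and 4 without WT at 24 hours replicate 2. The change of the genotype difference with time passed for no probe set (139 with an unadjusted p under 0.05, smallest adjusted p = 0.312, limma), and for 1 and 2 without KO at 24 hours replicate 1 and WT at 6 hours replicate 2. Among named genes Golm1, Clec2d, Wnt6, Fgf6 and Bdnf had the smallest p. The genotype differences at 6 and 24 hours, 6 hours and 8 days, and 24 hours and 8 days correlated across probe sets with r of -0.10, 0.11 and -0.12.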

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

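The tests in this part of explanations for Lgals3, the chemokines and the 6-hour genes, and the list tests of the change of the genotype difference, were chosen only after the results were seen.

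Among the lists, the KO minus WT difference of inflammatory chemokines and receptors was lower at 24 hours than at 6 hours (camera adjusted p = 0.0276, 22 of 25 genes negative, median -0.40). The adjusted p was 0.862 with an estimated correlation. It lay between 1.6e-04 and 0.307 when 1 of 12 arrays was left out, and was 0.307 and 0.0568 without WT at 6 hours replicates 1 and 3, 0.170 without KO at 6 hours replicate 3, 0.205 without WT at 24 hours replicate 2 and 0.305 without KO at 24 hours replicate 2. Cell markers moved the same way, with all 4 B cell markers (median -0.69), 9 of 10 NK and cytotoxic cell markers (median -0.35, camera adjusted p = 0.132) and 8 of 10 dendritic cell markers (median -0.17, camera adjusted p = 0.253) negative. The chemokine list means behind this difference were 6.45, 7.46 and 7.06 in WT and 7.27, 7.09 and 7.28 in KO at 6 hours. At 24 hours they were 6.98, 7.17 and 6.63 in WT and 6.72, 6.39 and 7.13 in KO, so its size also depends on single arrays. The same difference of C-type lectin receptors was lower too (adjusted p = 0.0295, 22 of 35 genes negative, median -0.11, and 0.862 with an estimated correlation). It lay between 0.00295 and 0.278 with 1 array left out, and was 0.278 and 0.0932 without WT at 6 hours replicates 1 and 3, 0.192 without KO at 6 hours replicate 3, 0.176 without WT at 24 hours replicate 1, and 0.0792 and 0.0710 without KO at 24 hours replicates 2 and 3.

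Lgals3 was detected on all arrays labelled knockout. Its lowest rank on any of the 18 arrays was the 90.0th percentile, which leaves an exchange of labels between the genotypes open, since a probe set that does not tell the genotypes apart cannot show one. The averaged KO minus WT difference of -0.37 leaves open that the probe set reads a part of the transcript that the knockout allele keeps, or another transcript. The lower end of its 95% confidence interval, -0.64, leaves open as well that the mice labelled knockout carried an intact gene. These explanations cannot be told apart, because the probe positions, the allele and the genotyping are not given in the sources used here.

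Of 25 inflammatory chemokine and receptor genes 9 were lower and 1 higher at 8 days than at 6 hours in each genotype. The list passed camera in KO (adjusted p = 0.00310), but not without the lowest 30% of probe sets, and in WT (adjusted p = 0.202) only after median centring or without WT at 6 hours replicate 1. It passed in neither genotype with an estimated correlation, and its change did not differ between the genotypes (adjusted p = 0.821). After median centring the members that fell still had a median of -2.13 in KO and -2.20 in WT (-2.17 and -2.27 as deposited). Array medians shifted by only -0.044 in KO and -0.076 in WT, so such a shift accounts for little of the fall. Centring can move a gene by no more than this, and the members were picked as lower in these data. Other effects of scaling were therefore not tested. The mean of NK and dendritic cell markers minus the mean of the chemokine list rose by 0.885 (two-sided exact permutation p = 0.005). That p is the smallest that 400 arrangements can give. The rise cannot decide on dilution by B cells, because the chemokine list was picked after its fall was seen. The NK list means at 6 hours, 4.69 to 5.04, also lay below the lowest array median of 5.95, which leaves less room for a fall. Dilution and fewer monocytes at 8 days stay open, as does a biological change with time. The first principal component held 36.7% of the variance, and time points processed in different batches cannot be told apart from time, because no processing dates are given in the sources used here.

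At 6 hours the 5 genes with the smallest p, Bdnf, Muc15, Cx3cl1, Frem1 and Fzd6, were all lower in the arrays labelled knockout, with a median of -0.75, and none passed. With the mean of the stromal and endothelial list as a covariate the median was -0.44, so more connective tissue in the WT samples may account for part of it and cannot be told apart from genotype. Without WT at 6 hours replicate 1 the median was -0.64, and Muc15 went from -1.76 to -1.001. The 5 genes were picked for their small p in this comparison, so neither value excludes that array as the cause, their joint direction is not evidence of a difference, and a difference by genotype stays open.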

How the results depend on the processing

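Leaving out the 2 farthest arrays and the title code block were chosen only after the data were seen. The replicate numbers did not pair the samples: arrays of different groups with the same number had a mean correlation of -0.04 over 45 pairs, against 0.02 over 90 pairs with different numbers. The cause of each change below was not tested, except that fits without arrays, or with only 2 groups, hold fewer arrays.

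For KO against WT at 6 hours array weights gave 8 probe sets and the fit without the 2 farthest arrays 3. For 24 hours against 6 hours in WT the 49 calls became 74 with median centring, 115 with array weights, 12 with the replicate block, 0 with only the 2 groups and 27 without the 2 farthest arrays. For 8 days against 6 hours in WT the 274 calls became 421, 89 and 177 with centring, only the 2 groups and without the 2 farthest arrays. In KO the 11 calls at 24 hours became 18 with centring, 137 with weights, 5 with only the 2 groups and 28 without the 2 farthest arrays, and the 141 calls at 8 days became 443 with weights and 92 with the replicate block. Of the 274 calls, 241 were shared with the centred fit and 145 with that without the 2 farthest arrays.

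Among the list counts, leaving out the lowest 30% of probe sets gave 1 list at 24 hours, 4 in place of 2 for KO against WT at 8 days and 0 in place of 2 for 8 days in KO. An estimated correlation and fry gave 0 in each of these last comparisons. Centring gave 1 list for 8 days in WT and 3 for KO against WT at 8 days, and the mean of the probe sets of a gene gave 3 for the latter.

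With 1 array left out, the counts ranged from 0 to 2 for KO against WT at 6 hours, 0 to 3 at 24 hours, 0 to 5 averaged and 0 to 2 for the change with time. They ranged from 7 to 78 for 24 hours in WT, 143 to 298 for 8 days in WT, 4 to 17 for 24 hours in KO and 47 to 158 for 8 days in KO. List counts ranged from 0 to 4 averaged, 0 to 1 at 6 hours, 0 to 3 at 24 hours, 0 to 3 at 8 days and 0 to 1 for 8 days in WT. The arrays that moved a count by over 1.5 times are named with each comparison. The 298 came without WT at 6 hours replicate 2, the 158 without KO at 8 days replicate 1, and the 3 lists at 8 days without WT at 8 days replicate 1.

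Genes of the fixed set that had not passed changed sign. At 6 hours Ifng was -0.021 with quantile normalization, -0.031 with weights and -0.21 without the 2 farthest arrays, Il4 was -0.066 with weights and -0.22 without the 2 farthest arrays, Notch1 was -0.017 and -0.0054 with the same settings, and Dll4 was -0.033 without the 2 farthest arrays. At 24 hours Tgfb1 was 8.8e-04 with centring, 0.035 with quantile normalization and 0.12 with weights, Notch1 0.024 with quantile normalization and Dll1 0.017 with weights. At 8 days Il10 was 0.0049 with quantile normalization and 0.030 with weights, and Jag1 0.0048 without the 2 farthest arrays. With 1 array left out the lowest and highest values at 6 hours were -0.33 and 0.10 for Il2ra, -0.24 and 0.17 for Tgfb1, -0.22 and 0.19 for Ifng, -0.22 and 0.24 for Il4, -0.094 and 0.25 for Notch1, -0.16 and 0.079 for Jag1, and -0.033 and 0.21 for Dll4. At 24 hours they were -0.24 and 0.13 for Il2ra, -0.11 and 0.14 for Tgfb1, -0.72 and 0.86 for Ifng, -0.14 and 0.052 for Notch1, -0.084 and 0.23 for Notch3, -0.23 and 0.16 for Jag1, and -0.30 and 0.011 for Dll1. At 8 days they were -0.084 and 0.078 for Il10, -0.034 and 0.17 for Notch3, -0.36 and 0.0048 for Jag1, and -0.083 and 0.14 for Dll1, and averaged -0.080 and 0.45 for Ifng. Of 152 values of named genes, 152 kept their direction and side of the threshold with the trended variance and with the title code block, 149 with centring, 145 with quantile normalization, 141 with weights, 138 with the replicate block and 134 without the 2 farthest arrays (12 weaker, 1 stronger and 5 reversed). With only the 2 groups 102 kept them and 28 were weaker, and without the lowest 30% of probe sets all 134 still tested kept them. Over all fits with 1 array left out 1035 values kept them, 104 were weaker, 4 stronger and 33 reversed.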

Other observations

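The tests of Ifng against NK markers and of the genes next to Lgals3 were chosen only after the data were seen, and the counts of other splits were planned.

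Siglech, a gene of plasmacytoid dendritic cells, was read by 3 probe sets of 1 transcript, which were higher in the arrays labelled knockout at 8 days by 0.74, 0.69 and 0.90, and none passed. At 24 hours all 4 B cell markers were lower in the arrays labelled knockout, and their change from 6 hours differed by a median of -0.69, with 2 of 4 past the threshold when adjusted over the list alone and none over all probe sets. At 24 hours 9 of 10 NK and cytotoxic, both T cell and 7 of 10 dendritic cell markers were lower as well, and 7 of 12 monocyte and macrophage markers higher. The mean of the B cell markers was 9.56, 9.05 and 9.31 on the KO arrays at 24 hours and 10.17, 9.80 and 9.83 on the WT arrays. Such a separation of 3 and 3 arrays is the outcome of 1 in 10 splits in either direction.

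Ifng, the cytokine of NK and Th1 cells, varied within groups, with 8.24 on WT at 24 hours replicate 2 and 7.51 on KO at 24 hours replicate 3. A hypothesis is that the share of NK cells differed between arrays of a group. Deviations of Ifng and of the mean of 10 NK and cytotoxic cell markers from their group means correlated over 18 arrays (Pearson r = 0.930, permutation p = 0.0039, Spearman rho = 0.829, permutation p = 0.0049). Without those 2 arrays r was 0.811 (permutation p = 0.031), but the deviations were still taken from group means that included them. This value therefore still depends on the 2 arrays and does not show whether the relation holds without them. The same 2 arrays also had the highest T cell, Th1 and chemokine list means of their groups (10.28, 8.06 and 7.17 in WT, and 10.20, 7.95 and 7.13 in KO). The Th1 list is that of the Th1 and interferon-gamma axis, so its mean is not separate from Ifng. High values on these 2 arrays were thus not particular to NK markers. Correlations of Ifng with the other lists were not computed, the share of NK cells stays open, and activation of the same cells was not tested. A further hypothesis was that a segment of the donor strain around Lgals3 differed in expression. The 10 measured genes nearest to Lgals3 had a median unadjusted p of 0.505 for the averaged genotype difference, at percentile 54.1 of 909 such sets. Of them 0 of 10 were under 0.05, which argues against a shift shared by those genes over the 3 times. Among these genes, Psmb5 was lower in KO at 8 days (-0.31, unadjusted p = 0.00164, adjusted p = 0.720, limma). An effect on single neighbours or at 1 time therefore stays open.

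Other splits of the same arrays were counted. The 6 arrays of a time or genotype give 10 splits, too few for a share under 0.05. For KO against WT the real count of probe sets was 0 at each time and the highest other count 1 at 6 hours, 5 at 24 hours and 1 at 8 days, and all 10 splits reach a count of 0 by construction. The highest other count was 2 against 49 for 24 hours and 2 against 274 for 8 days in WT, and 0 against 11 and 0 against 141 in KO, with 1 split as large in each. For the averaged difference and for its change with time all 100 splits drawn reach the real count of 0 by construction, so chance is not excluded, and the highest others were 1 and 3. Lists gave at most 8 in another split at 6 hours and 5 at 24 hours where the real count was 0, with all 10 splits as large. They gave 2 against a real 2 at 8 days and 3 against a real 2 for 8 days in KO, with 2 of 10 splits as large in each, 4 against 0 for 8 days in WT with all 10 as large, and 7 against 0 averaged with all 100 as large. The preset correlation of 0.01 lies below the estimated correlation of 0.432 for the chemokine list and 0.638 for the NK list, and whether this or a structure of the samples gave the lists called in other splits was not tested.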
